A study of Mus musculus with 9 samples.

How the data were processed

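RNA was measured in 9 libraries of sorted mouse skin cells, 3 in each of the groups Quiescent, Active and UVB, which were taken from the labels together with the replicate numbers. Per the labels' protocols, libraries were made from total RNA by poly(A) selection with a directional kit. The submitters' processing notes name cutadapt 1.8, a trimmer of adapters, TopHat2 2.0.13, a spliced aligner, Cuffdiff 2.2.1 and the genome build mm10. How these were run, the gene annotation and the strand setting are not given in the sources used here. A directional kit keeps the strand of the RNA, but without the setting it is open whether overlapping genes on opposite strands were told apart.

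The deposited table has the columns of a Cuffdiff read group tracking table, per the file headers, with 1 row per gene and library. Its estimated counts are the authors' fragments per gene before scaling between libraries, and 1.08% of the 210249 values, in 334 genes, were not whole to within 1e-06, which fits fragments shared between genes. The authors' FPKM values are fragments per kilobase of transcript and per library total after their own scaling between libraries: per fragment they stood at 1.51 times the level of Quiescent replicate 1 in the other Quiescent libraries and at 0.79 to 1.03 times in Active and UVB. Cuffdiff marked 18 values in 7 genes as failed, and these were used as listed. All rows had a gene name and belonged to 1 of the 9 libraries. Poly(A) selection and trimming act on every library alike, whereas fragments from close copies of a gene are assigned by the counting model, so members of such families are reported as uncertain.

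Library totals ran from 21045071 to 35131778 fragments. A gene with 0 fragments in a group was given an upper limit of 3 fragments over the group, and folds against such a group are lower bounds from that limit, also when leaving out a library leaves the group at 0. Such limits cover counting error only, since polymerase chain reaction copies are not independent molecules. Libraries of 1 group differed by more than sampling noise, with a chi-square per degree of freedom of 25.6 to 120.2 and r of 0.977 to 0.990 between log2 counts across genes.

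The estimated counts were rounded and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, TMM scaling factors, 1 fit of all 9 libraries with a mean per group). The edgeR function filterByExpr removed 8283 of 23361 genes and left 15078. Adjusted p-values are Benjamini-Hochberg values over all genes tested, two-sided, with a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of F. The replicate coefficient of variation was 0.28. TMM factors were 0.660 to 0.748 in Quiescent and 1.163 to 1.225 in the other groups. Levels are CPM, counts divided by the scaled library total and multiplied by 1e+06.

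A set of 36 gene lists was fixed before the data were examined, covering the pigment lineage, the cell cycle, damage and immune responses, signalling pathways, metabolism, other skin cell types and RNA quality. Older symbols were matched through the RefSeq table of the same build. The 33 lists with at least 5 tested members were tested with limma 3.58.1 (camera, a competitive test, with preset correlation 0.01 and again with an estimated correlation), on voom log2 CPM. No mitochondrially encoded gene was listed under its usual symbol, so that list was not analysed. Some genes stand in more than 1 list, such as Thy1 for fibroblasts and T cells.

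Genes were named by a rule fixed before the data were examined. It gives Hmga2, Kit, Mitf, Tyr, Braf and Mki67 in every comparison, and 1 more gene that is not reported here. It adds the 8 higher and 8 lower genes with the largest fold change among those past the threshold, with mean log2 CPM of at least 2 and no overlap between the libraries of the groups, predicted genes left out. From each list it takes up to 4 members with the smallest adjusted p, or up to 2 of the most abundant where none passes. The text names a part of these. For 3 libraries against 3, chance gives non-overlap in 10% of genes. Sox10 and Dct were added after their values were seen, as were single values quoted for 1 library and the genes named among those with opposite calls.

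The tests were tried on simulated data with the real means and library sizes. In each comparison 67, 67 and 66 genes were changed by 1.5, 2 and 4 times. For Active against Quiescent, 3.0%, 37.3% and 78.8% of genes changed by 1.5, 2 and 4 times were recovered among 14939 tested, with 3 false calls. For UVB against Quiescent these shares were 1.5%, 35.8% and 77.3% among 14925, with 5 false calls, and for UVB against Active 0.0%, 29.9% and 80.3% among 14904, with 4 false calls. A raised list was called in each comparison, and none of 30 random lists.

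Alternatives fixed in advance were other scaling factors, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), no filter and a stricter filter of 50 counts in 3 libraries, a fit of only the groups compared, each library left out in turn, and a replicate block. Added after the data were examined were library size alone, leaving out the genes of chromosomes X and Y, leaving out the fibroblast list before scaling, leaving out Quiescent replicate 2 and UVB replicate 3 together, and edgeR's glmTreat for a change beyond 2-fold. Of the genes tested, 99.6% could be placed on a chromosome. Overlap of calls was set beside 20 simulations of unchanged groups. Intervals for list medians are 95% bootstrap intervals over members from 10000 resamples. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.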

Results

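Poly(A)-selected RNA was sequenced from mouse skin cells that were sorted by flow cytometry and labelled as melanocyte stem cells, the reserve cells of the hair follicle from which pigment cells are renewed. The mice carried a genotype labelled TBPT and were 10 weeks old. The 9 libraries formed 3 groups of 3, named Quiescent, Active and UVB, where UVB is the medium-wave ultraviolet band of sunlight. The treatment label named chemical depilation or UVB for every sample alike, so which group was depilated was not stated. The fragments assigned to genes numbered 35131778, 22448079 and 25660627 in the Quiescent libraries, 26193564, 22923373 and 21045071 in Active, and 27253531, 24601655 and 25255600 in UVB. Of 23361 genes in the table, 15078 had enough fragments to be tested. Each library was counted as its own replicate, after its replicate label. Libraries of the same group differed by more than sampling noise, but separately prepared libraries of 1 sample can do so too. The labels do not say that they came from separate animals, and p-values therefore measure only the spread between these libraries. Levels below are CPM, counts relative to the scaled library total, as mean ± SD with n = 3 libraries per group, and adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested.

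The libraries differed first in which genes filled them. The collagen genes Col1a1, Col1a2 and Col3a1, abundant products of dermal fibroblasts, took 26.27%, 23.23% and 27.71% of the fragments in the Quiescent libraries, 0.55%, 0.70% and 0.65% in Active, and 3.12%, 2.45% and 3.49% in UVB. The 10 most abundant genes took up to 35.9% of a Quiescent library and at most 6.8% of an Active or UVB library. Xist, the X-inactivation transcript of female cells, had 23353 to 30356 fragments in each UVB library and 4 to 12 in every other library. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 4106 to 5591 fragments in each Quiescent and Active library, 2 in UVB replicate 1, and 0 in UVB replicates 2 and 3. The UVB group thus differed from both other groups in its sex-linked transcripts as well as in its label. Xist overlaps an antisense gene, and the strand setting of the authors' counting is not given in the sources used here. The first principal component of the log2 CPM values held 65.6% of the variance and set Quiescent apart from the rest, and the second held 19.0% and set UVB apart from Active.

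The Active and Quiescent groups were compared to ask what distinguishes cells labelled as active melanocyte stem cells from those labelled as quiescent. Genes of the pigment lineage and of cell division were far higher in Active, while genes of dermal fibroblasts, vessels and muscle were far lower. Tyr, which encodes tyrosinase, the rate-limiting enzyme of melanin synthesis, rose from 2.02 ± 0.517 CPM in Quiescent to 475 ± 176 CPM in Active, a log2 fold change of 7.89 ± 0.40 (SE) with adjusted p = 3.0e-06. Kit, the receptor for stem cell factor, rose 30.7-fold from 3.98 ± 2.09 to 124 ± 29.6 CPM (adjusted p = 4.4e-05). Mitf, the central transcription factor of the melanocyte lineage, rose 3.82-fold (adjusted p = 0.005), with 210 ± 146 CPM in Active against 55.0 ± 8.44 CPM in Quiescent, and 2.29-fold without Active replicate 1. Sox10 and Dct, a neural crest transcription factor and a melanin synthesis enzyme, were picked out after their values were seen. Sox10 stood at 2.16 ± 1.85 CPM in Quiescent and 591 ± 60.6 CPM in Active, and Dct at 17.6 ± 15.1 and 5570 ± 1440 CPM (adjusted p = 2.8e-05 and 1.4e-04). Their folds of 263 and 316 became 472 for Sox10 without Quiescent replicate 1 and 533 for Dct without Quiescent replicate 2.

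Of the 20 pigment synthesis and melanosome genes, 17 rose and 2 fell, with the same counts adjusted over the list alone. Slc45a2 and Mc1r, a melanosomal transporter and the melanocortin receptor, rose by 8.47 ± 0.52 and 6.24 ± 0.53 on the log2 scale. The list passed limma's camera test (adjusted p = 5.9e-05), and adjusted p = 0.729 with an estimated correlation. Among 22 neural crest and melanoblast factors, 15 rose and 3 fell (15 and 4 adjusted over the list alone). The nerve growth factor receptor gene Ngfr rose 71-fold to 185 ± 39.9 CPM, Mcam 17.6-fold to 849 ± 32.0 CPM, and Foxd3, a neural crest transcription factor, from 0.177 ± 0.102 to 219 ± 96.0 CPM. That list had camera adjusted p = 9.0e-04, and adjusted p = 0.729 with an estimated correlation.

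Cell division genes moved as a block. All 28 mitosis genes rose, and so did 27 of 28 DNA replication genes, with the same counts adjusted over each list alone. Mki67, a marker of cycling cells, rose 28.7-fold from 10.5 ± 4.37 to 301 ± 66.2 CPM (adjusted p = 5.3e-05). Ccnb2, a mitotic cyclin, rose 37.1-fold and Rrm2, a subunit of ribonucleotide reductase, 31.6-fold. Both lists had camera adjusted p = 1.2e-09, and adjusted p = 0.729 with an estimated correlation. Of 19 genes that report MAPK pathway output, 12 rose and 1 fell (12 and 2 adjusted over the list alone), among them Ccnd1 (10.9-fold), Etv1 (9.38-fold) and Dusp6 (9.05-fold). Their camera adjusted p was 0.003, and adjusted p = 0.729 with an estimated correlation. Hmga2, a chromatin architectural protein, averaged 2.94 ± 0.374 CPM in Quiescent and 8.49 ± 4.46 CPM in Active (log2 fold change 1.53 ± 0.42, adjusted p = 0.012). Its Active values were 12.0, 10.0 and 3.5 CPM, so replicate 3 lay close to the Quiescent level. The kinase gene Braf had 37.9 ± 6.64 and 32.9 ± 0.529 CPM (adjusted p = 0.222). Braf passed the test without Quiescent replicate 1 (adjusted p = 0.021).

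All 16 dermal fibroblast genes were lower in Active, also when adjusted over the list alone. Col1a1 was 165-fold lower (log2 fold change -7.37 ± 0.32, adjusted p = 2.0e-06), at 118000 ± 17900 CPM in Quiescent and 714 ± 90.8 CPM in Active, and Col3a1 was 29.8-fold lower. Of 13 endothelial genes 12 were lower and 1 higher, with Tek 49.2-fold and Kdr 18-fold lower, and all 11 muscle genes were lower, with Myh11 17.9-fold lower. Both counts were the same adjusted over each list alone. Camera adjusted p was 1.2e-09, 3.1e-05 and 3.9e-05 for the fibroblast, endothelial and muscle lists, and adjusted p = 0.729 with an estimated correlation for each. Of 19 myeloid and Langerhans genes 12 were lower (13 adjusted over the list alone), with Csf1r at 250 ± 242 CPM in Quiescent and 8.25 ± 4.25 CPM in Active. Quiescent replicate 2 had 529.1 CPM of Csf1r against 121.6 and 99.3 CPM in the other two, and without it Csf1r was 13.3-fold lower in place of 30.2-fold. Camera did not pass the list (adjusted p = 0.119, and adjusted p = 0.892 with an estimated correlation), but passed it as lower without Quiescent replicate 3 (adjusted p = 0.0082). Interferon response genes were lower for 19 of 32 members and higher for 1, and inflammatory and NF-kB target genes lower for 14 of 23 and higher for 1, each with the same counts adjusted over the list alone. Usp18 was 16.2-fold and Csf1 18.6-fold lower. Each of these lists had camera adjusted p = 0.002. With an estimated correlation, adjusted p = 0.729 for the interferon list and adjusted p = 0.753 for the NF-kB list. Genes of the growing hair matrix and inner root sheath went the other way: 15 of 23 rose (16 adjusted over the list alone), with Tchh, which encodes trichohyalin, at 4.09 ± 3.09 CPM in Quiescent and 90.9 ± 71.8 CPM in Active (camera adjusted p = 0.002, and adjusted p = 0.753 with an estimated correlation). The 22.5-fold rise of Tchh became 39.6-fold without Quiescent replicate 2 and 12.9-fold without Active replicate 2. T cell and mast cell lists had no common direction, with 1 gene higher and 2 lower of 11, and 2 lower of 12 (1 and 1, and 2, adjusted over each list alone). The mast cell median of -0.12 changed sign with library size alone, and the T cell median of 0.04 stood beside a mean of -0.24.

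By the naming rule, the genes with the largest increases were Foxd3 and 7 genes outside these lists. Cntn6, Nppb and Cdh10, which encode a contactin, a natriuretic peptide precursor and a cadherin, had 0 fragments in the Quiescent libraries and 134 ± 8.93, 34.5 ± 10.7 and 26.2 ± 6.64 CPM in Active. Against a floor of 3 fragments over the group they were at least 2660-fold, 691-fold and 507-fold higher. Ecel1, an endothelin-converting enzyme-like peptidase, rose from 0.958 ± 0.369 to 1200 ± 333 CPM. Lrrc4b and Car6 reached 26.9 ± 3.59 and 67.2 ± 10.8 CPM from below 0.1 CPM. Alpi reached 81.1 ± 23.2 CPM, but belongs to a family of close copies, so its count is uncertain. At the other end, the tissue kallikrein genes Klk1, Klk1b21, Klk1b27, Klk1b24 and Klk1b1 had 1800 ± 1260, 785 ± 562, 612 ± 744, 511 ± 462 and 134 ± 126 CPM in Quiescent, and at most 1 fragment in Active. They are near-identical copies whose fragments the authors' counting could split, so the level of each member is uncertain. Pgr, the progesterone receptor gene, fell from 171 ± 29.3 to 0.105 ± 0.132 CPM, and Rnase10 from 31.4 ± 7.24 CPM to below 0.1 CPM. Folds against so few fragments moved with single libraries. Lrrc4b and Car6 went from 1230-fold and 1200-fold to 780-fold and 718-fold without Quiescent replicate 1. Without Quiescent replicate 3, which held their only Quiescent fragments, they were at least 375-fold and 958-fold higher. Alpi went from 1110-fold to 657-fold without Quiescent replicate 1. Klk1b21, Klk1b27, Klk1b24 and Klk1b1, at 0 fragments in Active, were at least 21000-fold, 15600-fold, 13500-fold and 3540-fold lower, and without Quiescent replicate 3 at least 13400-fold, 5290-fold, 7200-fold and 1840-fold. Klk1 had 1 fragment in Active. Its fitted fold of 108000 became 65100 without Quiescent replicate 3, and it was at least 29800-fold lower without Active replicate 1, which held that fragment. Rnase10 was 784-fold lower, and at least 536-fold without Active replicate 1, which held its only Active fragments. Pgr went from 1530-fold to 4260-fold without Active replicate 2.

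In all, 4390 genes were higher and 4396 lower in Active than in Quiescent, 58.3% of those tested, and 15 of 33 gene lists passed camera with its preset correlation. None of the lists passed with an estimated correlation, where 1 had an unadjusted p under 0.05 and the lowest adjusted p was 0.729. With library size alone in place of the scaling factors, an alternative chosen after the data were examined, 8651 genes were higher and 2206 lower, because the median log2 fold change of all genes moved from 0.007 to 0.757.

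**Figure D1:**
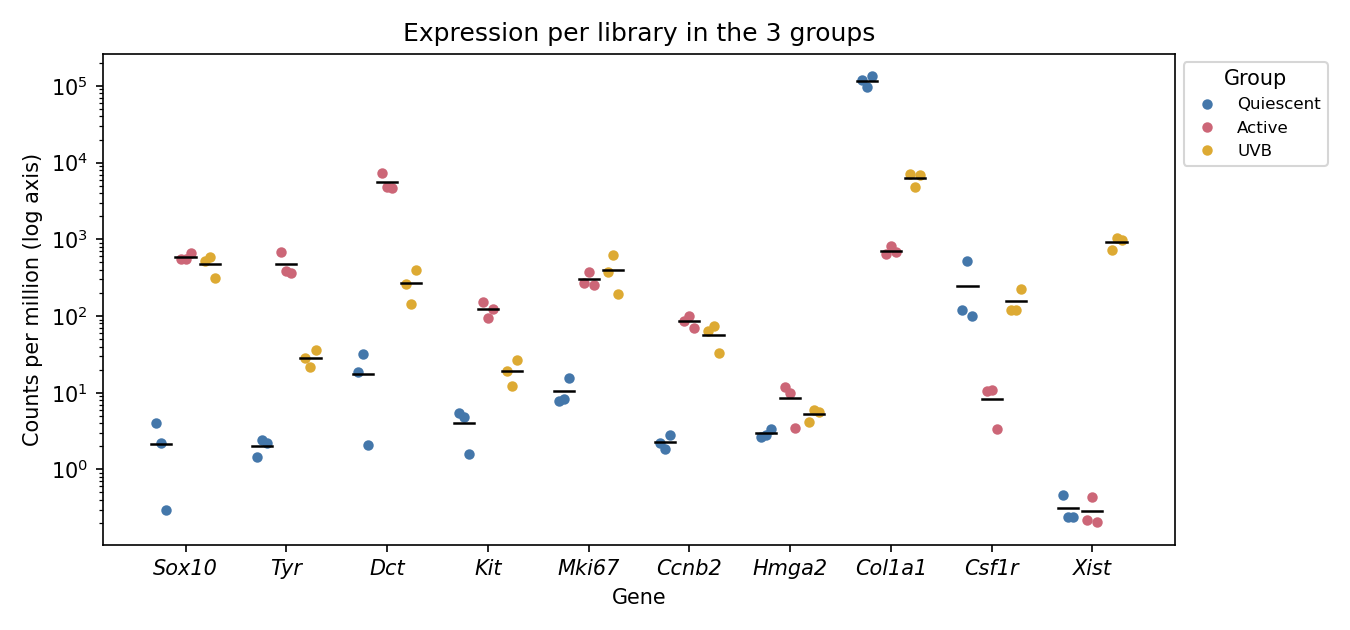
CPM of 10 genes in each of the 9 libraries, on a log axis. Points are libraries, coloured by group, and black bars are group means (n = 3). Sox10 averaged 2.16 CPM in Quiescent, 591 CPM in Active and 474 CPM in UVB, Tyr 2.02, 475 and 28.8 CPM, and Col1a1 118000, 714 and 6320 CPM.

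The UVB group was set against Quiescent to ask which of these differences appear after ultraviolet exposure. Lineage and division genes were again far higher, pigment genes rose less than in Active, and fibroblast genes were lower by a smaller factor. Tyr rose 14.4-fold to 28.8 ± 7.55 CPM (log2 fold change 3.85 ± 0.35, adjusted p = 6.0e-05), and Kit 4.81-fold to 19.4 ± 7.22 CPM (adjusted p = 0.003). Mitf had 27.3 ± 9.58 CPM against 55.0 ± 8.44 CPM (adjusted p = 0.088). It passed the test without Active replicate 1, a library outside this comparison that shares the estimate of spread (adjusted p = 0.011). Sox10 stood at 474 ± 142 CPM, 211-fold above Quiescent (adjusted p = 6.2e-05), and Dct at 267 ± 127 CPM, 15.2-fold above it (adjusted p = 0.004). These folds became 378 for Sox10 without Quiescent replicate 1 and 25.6 for Dct without Quiescent replicate 2.

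Of the 20 pigment genes 14 rose and 3 fell, the same counts as when adjusted over the list alone, with Mc1r 23.4-fold and Mlph 11.9-fold higher and Bace2 12.9-fold lower. Camera did not pass that list (adjusted p = 0.088, and adjusted p = 0.803 with an estimated correlation), but passed it without UVB replicate 2 (adjusted p = 0.033). Of the 22 neural crest and melanoblast factors 15 rose and 2 fell, with the same counts adjusted over the list alone. Ngfr rose 62.2-fold to 162 ± 24.2 CPM and Nes 26.1-fold to 254 ± 43.1 CPM. The list had camera adjusted p = 1.7e-04, and adjusted p = 0.803 with an estimated correlation. All 28 mitosis genes and 27 of 28 DNA replication genes rose, also adjusted over each list alone. Mki67 rose 38.2-fold to 399 ± 218 CPM (adjusted p = 7.5e-05), Ccnb2 24.9-fold and Mcm5, a subunit of the replicative helicase, 15.7-fold. Camera adjusted p was 8.6e-10 for mitosis and 8.4e-09 for replication, and adjusted p = 0.803 with an estimated correlation for both. MAPK output genes rose for 12 of 19 members, also adjusted over the list alone, with Etv1 11.3-fold, Ccnd1 9.43-fold and Spry4 4.8-fold higher (camera adjusted p = 4.5e-04, and adjusted p = 0.803 with an estimated correlation). Hmga2 had 5.23 ± 1.01 CPM against 2.94 ± 0.374 CPM (log2 fold change 0.83 ± 0.42, adjusted p = 0.129). Hmga2 passed without Active replicate 3 in the joint fit (adjusted p = 0.023). Braf had 45.1 ± 2.33 CPM against 37.9 ± 6.64 CPM (adjusted p = 0.146).

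Dermal fibroblast genes were lower in UVB for 12 of 16 members and higher for 2 (12 and 3 adjusted over the list alone). Col1a1 and Col1a2 were both 18.6-fold lower, at 6320 ± 1300 and 7080 ± 2120 CPM. The list had camera adjusted p = 2.3e-04, and adjusted p = 0.803 with an estimated correlation. All 11 muscle genes were lower, with Myh11 8.28-fold lower, and 8 of 13 endothelial genes were lower and 1 higher, with Tek 6.03-fold lower (11, and 9 and 1, adjusted over each list alone). Camera adjusted p was 1.3e-05 and 0.010, and adjusted p = 0.803 with an estimated correlation for both. Of 11 T cell genes 9 rose and 1 fell, and 8 of 12 mast cell genes rose, with the same counts adjusted over each list alone. Cd3g, a subunit of the T cell receptor complex, rose from 0.184 ± 0.127 to 5.17 ± 1.59 CPM (26.1-fold, and 41.9-fold without Quiescent replicate 1), and the mast cell protease genes Tpsb2 and Cpa3 rose 24.5-fold and 10.8-fold to 14.6 ± 8.12 and 17.7 ± 7.11 CPM. Tpsb2 has a close paralog, so its count is uncertain. The T cell list had camera adjusted p = 0.009 and the mast cell list 0.005, and adjusted p = 0.803 with an estimated correlation for both. Of 19 myeloid and Langerhans genes 2 passed the test (1 adjusted over the list alone), led by Itgax with 2.01 ± 2.15 and 33.3 ± 12.5 CPM (16.7-fold, and 36.5-fold without Quiescent replicate 2). The list had camera adjusted p = 0.019, and adjusted p = 0.803 with an estimated correlation. Camera no longer passed it without Quiescent replicate 1 or 3 (adjusted p = 0.06 and 0.11) or without UVB replicate 3 (adjusted p = 0.067). Interferon response genes were split, with 6 higher and 5 lower of 32, the same counts adjusted over the list alone.

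Of the 8 genes with the largest increases by the naming rule, 6 were also among the 8 of Active against Quiescent. Cntn6, Nppb and Cdh10 were at least 1800-fold, 569-fold and 335-fold higher than the Quiescent floor, Ecel1 reached 1450 ± 497 CPM, Foxd3 171 ± 66.2 CPM, Lrrc4b 25.0 ± 2.22 CPM, and Crym, a thyroid hormone binding protein, rose 580-fold to 210 ± 76.3 CPM. Xist rose from 0.315 ± 0.134 to 919 ± 161 CPM. The largest decreases were the kallikreins, of which Klk1, Klk1b21 and Klk1b1 had 0 fragments and Klk1b27 and Klk1b24 had 3 and 4 fragments in UVB, and the Y-linked genes. Eif2s3y and Kdm5d had 0 fragments in UVB and were at least 1750-fold and 955-fold lower than in Quiescent, and Ddx3y had 1 fragment against 7737. Without UVB replicate 1, which held that fragment, Ddx3y was at least 2560-fold lower. Klk1b27 went from 16200-fold to 4840-fold lower without Quiescent replicate 3, and was at least 10900-fold lower without UVB replicate 1, which held its only UVB fragments. Klk1b24 went from 10400-fold to 5030-fold without Quiescent replicate 3 and to 23900-fold without UVB replicate 3. Klk1, Klk1b21 and Klk1b1 were at least 51800-fold, 22600-fold and 3810-fold lower, and without Quiescent replicate 3 at least 33300-fold, 14400-fold and 1980-fold. Lrrc4b went from 1150-fold to 724-fold higher without Quiescent replicate 1, and was at least 353-fold higher without Quiescent replicate 3.

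A total of 3895 genes were higher and 3498 lower in UVB than in Quiescent, 49.0% of those tested, and 12 of 33 lists passed camera. With an estimated correlation no list passed, none had an unadjusted p under 0.05, and the lowest adjusted p was 0.803. With library size alone, 8746 genes were higher and 1246 lower, and the median log2 fold change of all genes moved from 0.021 to 0.742.

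The overlap of both comparisons with Quiescent asks how far the Active and UVB groups differ from Quiescent in the same genes. Of the 15078 genes, 3152 were higher and 2807 lower in both, 5959 in all. Independent lists of the same lengths would share 2154. Simulated groups that did not differ from the shared Quiescent libraries shared 0 in each of 20 simulations. With no changed genes to call, those simulations set no benchmark for the size of the overlap. The log2 fold changes correlated at r = 0.815 across genes, against 0.502 in the simulations, where the shared libraries alone were at work. Their covariance was 2.93 against a simulated 0.083, a difference of 2.84. Genes are not independent replicates, and part of the excess may come from the shared Quiescent libraries, which are too few to split.

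The direct comparison of UVB with Active asks how cells after ultraviolet exposure differ from cells in the active state. Pigment genes were lower in UVB, genes of fibroblasts, vessels, myeloid cells, T cells and mast cells were higher, and lineage and division genes differed little by median. Of 20 pigment genes 16 fell and none rose (17 and 0 adjusted over the list alone). Tyr was 16.5-fold lower (log2 fold change -4.04 ± 0.33, adjusted p = 3.7e-04), Slc45a2 17.5-fold, Dct 20.8-fold and Mlph, which links melanosomes to their motor, 5.23-fold. The list had camera adjusted p = 2.2e-13, and adjusted p = 0.445 with an estimated correlation. Mitf was 7.7-fold and Kit 6.38-fold lower, both with adjusted p = 0.004, and Mitf was 4.62-fold lower without Active replicate 1. Of the 22 neural crest and melanoblast factors, 3 rose and 2 fell, the same counts as adjusted over the list alone. Notch2 and Axl rose 2.08-fold and 1.68-fold, and the median log2 fold change of the list was -0.19 (camera adjusted p = 0.867, and adjusted p = 0.935 with an estimated correlation). Sox10 had 474 ± 142 CPM in UVB and 591 ± 60.6 CPM in Active (adjusted p = 0.686). Of the 28 mitosis genes, 0 passed in edgeR, also adjusted over the list alone, 0 in DESeq2, and 1 had an unadjusted p under 0.05. Of 28 DNA replication genes, 2 were lower (1 adjusted over the list alone). The list medians were -0.32 and -0.52, with camera adjusted p = 0.013 and 3.6e-05. With an estimated correlation, adjusted p = 0.771 for mitosis and adjusted p = 0.603 for replication. Camera no longer passed the mitosis list without Active replicate 2 (adjusted p = 0.11), without UVB replicate 3 (0.83), or without UVB replicate 3 and Quiescent replicate 2 together (0.8). Mki67 had 399 ± 218 CPM in UVB and 301 ± 66.2 CPM in Active (adjusted p = 0.507), and Top2a, a topoisomerase of dividing cells, 417 ± 229 and 469 ± 87.8 CPM (adjusted p = 0.807). UVB replicate 3 had the lowest Mki67 of its group, 196.7 CPM against 371.0 and 630.6 CPM.

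Dermal fibroblast genes rose for 15 of 16 members and endothelial genes for 12 of 13, with the same counts adjusted over each list alone. Col1a1 was 8.86-fold higher, Thy1 11.3-fold, and the vascular receptor genes Flt1 and Kdr 19.4-fold and 9.21-fold. Camera adjusted p was 2.2e-13 and 3.9e-08, and with an estimated correlation adjusted p = 0.445 and adjusted p = 0.479. Myeloid and Langerhans genes rose for 17 of 19 members, T cell genes for 10 of 11 and mast cell genes for 10 of 12 (19, 11 and 10 adjusted over each list alone). Csf1r, the receptor of macrophage colony-stimulating factor, rose 18.9-fold to 156 ± 60.9 CPM, Cd247 8.98-fold to 2.39 ± 0.525 CPM and Cpa3 10.4-fold to 17.7 ± 7.11 CPM. In the same order, camera adjusted p was 6.4e-07, 6.6e-07 and 1.3e-06. With an estimated correlation, adjusted p = 0.492, adjusted p = 0.445 and adjusted p = 0.479. Interferon response genes rose for 16 of 32 members (22 adjusted over the list alone), with Oasl2 4.21-fold and Ifih1, a sensor of viral RNA, 2.4-fold higher. Inflammatory and NF-kB target genes rose for 13 of 23 (15 adjusted over the list alone), with Ptgs2, the inducible cyclooxygenase, 5.3-fold higher. Neither list had a member that fell. Camera adjusted p was 1.3e-07 and 3.6e-05, and with an estimated correlation adjusted p = 0.479 and adjusted p = 0.492.

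Hair matrix and inner root sheath genes were lower for 10 of 23 members, also adjusted over the list alone, and Tchh was 28.4-fold lower at 3.19 ± 2.41 CPM (camera adjusted p = 8.8e-07, and adjusted p = 0.492 with an estimated correlation). The fold of Tchh became 16.3 without Active replicate 2 and 47.8 without UVB replicate 3. Suprabasal and stress keratinocyte genes were lower for 3 of 16 members (4 adjusted over the list alone) and higher for none, with camera adjusted p = 1.6e-04, and adjusted p = 0.492 with an estimated correlation. Among genes that answer to ultraviolet damage, 4 of 28 p53 targets rose and 2 fell, and 1 of 25 nucleotide excision repair genes rose and 1 fell (4 and 2, and 1 and 0, adjusted over each list alone). Camera passed neither (adjusted p = 0.330 and 0.078, and adjusted p = 0.603 and adjusted p = 0.492 with an estimated correlation), but it passed the repair list as lower without UVB replicate 2 (adjusted p = 0.028). Both lists had more calls against Quiescent, but so did all genes. Of those tested, 58.3% were called in Active and 49.0% in UVB against Quiescent, and 24.0% in UVB against Active. More calls alone therefore do not single out these lists. Repair genes rose for 12 and fell for 3 in Active, and rose for 11 in UVB, also adjusted over the list alone. Their camera adjusted p was 0.037 and 0.097, and adjusted p = 0.729 and adjusted p = 0.803 with an estimated correlation. The call in Active was lost without Quiescent replicate 2 (adjusted p = 0.059), and without it and UVB replicate 3 (0.053). Targets of p53 rose for 9 and fell for 10 in Active, and rose for 10 and fell for 5 in UVB (9 and 10, and 11 and 6, adjusted over the list alone), with camera adjusted p = 0.824 and 0.291, and adjusted p = 0.892 and adjusted p = 0.803 with an estimated correlation. Hmga2 had 5.23 ± 1.01 CPM in UVB and 8.49 ± 4.46 CPM in Active (adjusted p = 0.242). Without Active replicate 3, whose 3.5 CPM lay below every UVB library, Hmga2 passed with adjusted p = 0.027. Braf was 1.37-fold higher in UVB (adjusted p = 0.038). Braf lost its call when any 1 of the 6 libraries compared was left out (adjusted p from 0.061 to 0.12).

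By the naming rule, the 8 genes with the largest increases were Xist (919 ± 161 CPM against 0.286 ± 0.129 CPM), Ccl17, Crp, Ear2, Alox15, Ccl22, Retnla and Cd163. Ccl17 and Ccl22, chemokines that attract T cells, rose 118-fold to 24.4 ± 13.9 CPM and 48.5-fold to 48.6 ± 31.9 CPM. Alox15, a lipoxygenase of alternatively activated macrophages, rose 62.9-fold, and Ear2, an eosinophil-associated ribonuclease with close paralogs and thus an uncertain count, rose 65.7-fold. Without UVB replicate 1 the folds of Ccl22 and Alox15 became 30.9 and 36.8, and without UVB replicate 3 that of Ear2 became 39.5. The 75.3-fold rise of Crp became 14.4-fold without UVB replicate 3, and was at least 36.6-fold without Active replicate 1, which held its only Active fragments, and the 35.7-fold rise of Cd163 became 20.5-fold without UVB replicate 3. Crp, Retnla and Cd163 each lost their call without any 1 of the Active libraries (adjusted p from 0.073 to 0.12). Retnla also lost its call without UVB replicate 1, 2 or 3 (adjusted p = 0.078, 0.066 and 0.086), and Cd163 without UVB replicate 1 or 3 (adjusted p = 0.053 and 0.065). The 8 largest decreases were the Y-linked Eif2s3y, Kdm5d, Ddx3y and Uty, then Krt33a, Krtap11-1, Fetub and Krtap7-1. Fetub, which encodes fetuin-B, fell 97.3-fold from 16.6 ± 3.07 to 0.165 ± 0.0541 CPM. Eif2s3y and Kdm5d were at least 1470-fold and 799-fold lower. Ddx3y and Uty were 4510-fold and 1130-fold lower, and at least 1400-fold and 351-fold without UVB replicate 1, which held their only UVB fragments. The hair keratin and keratin-associated genes belong to families of close copies, and their calls rested on few libraries. Krt33a lost its call without Active replicate 2 or UVB replicate 1 (adjusted p = 0.063 and 0.051) and Krtap7-1 without UVB replicate 1 (adjusted p = 0.053). Krtap11-1 lost it without Active replicate 1 or 2 or UVB replicate 1 or 2 (adjusted p from 0.053 to 0.1). Without Active replicate 2 the folds of Krt33a, Krtap11-1 and Krtap7-1 went from 234, 114 and 89.1 to 78.3, 43.2 and 26.8. Those of Krt33a and Krtap11-1 were 156 and 76 without UVB replicate 1, and at least 498 and 295 without UVB replicate 3, which held their only UVB fragments.

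In this comparison 2226 genes were higher and 1386 lower in UVB, 24.0% of those tested, and 16 of 33 lists passed camera. With an estimated correlation no list passed, 3 had an unadjusted p under 0.05, and the lowest adjusted p was 0.445. The 3612 calls fell to 1806 without Active replicate 1, to 1452 without Active replicate 2 and to 1938 without UVB replicate 1, and 826 genes passed a test for a change beyond 2-fold, against 3599 in Active against Quiescent and 2317 in UVB against Quiescent.

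**Figure D2:**
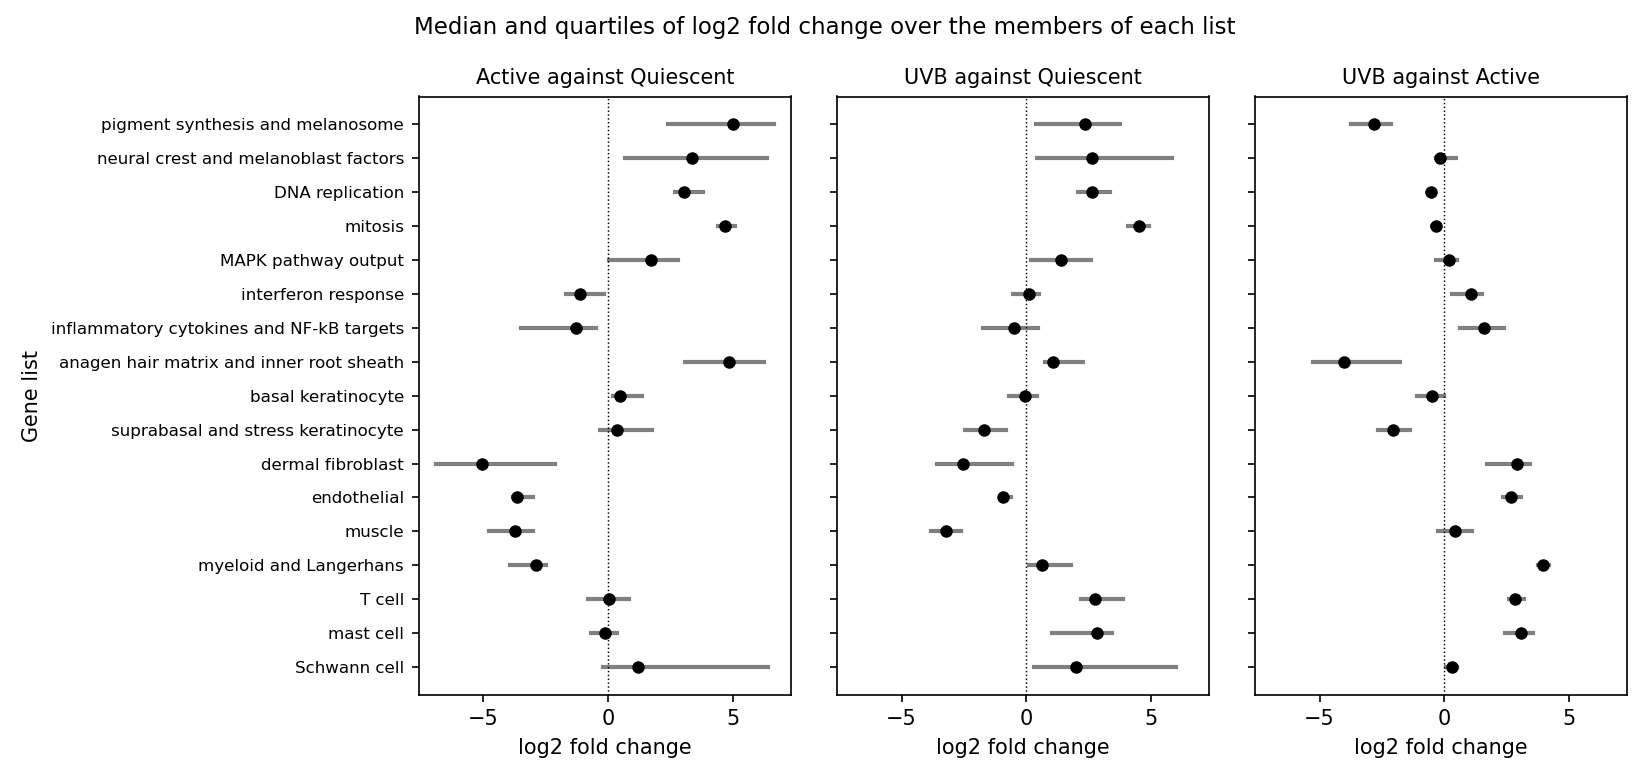
Median log2 fold change over the members of 17 gene lists in each of the 3 comparisons. Points are medians and grey bars run from the lower to the upper quartile of the members, so they show the spread of genes and not replicate error. With library size alone, the medians of the mast cell list in Active against Quiescent and of the NF-kB and basal keratinocyte lists in UVB against Quiescent changed sign. In UVB against Active the pigment list lay at -2.82 and the neural crest and melanoblast list at -0.19, while the myeloid, T cell and mast cell lists lay at 3.95, 2.84 and 3.08.

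Positions are given on the mouse genome build mm10 (GRCm38), from GENCODE release M21, with start and end of the whole gene including exons, introns and untranslated regions. Tyr lies on chromosome 7 from 87424771 to 87493512, Kit on chromosome 5 from 75574916 to 75656722, and Mitf on chromosome 6 from 97807052 to 98021349. Sox10 lies on chromosome 15 from 79154908 to 79165240, Dct on chromosome 14 from 118012790 to 118052244, and Mki67 on chromosome 7 from 135689784 to 135716361. Hmga2 lies on chromosome 10 from 120361275 to 120476469, and Braf on chromosome 6 from 39603237 to 39725463. Col1a1 lies on chromosome 11 from 94936224 to 94953042. All of these are protein-coding genes, and Xist, on chromosome X from 103460366 to 103483254, is a long noncoding RNA.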

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

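The tests of explanations in this part were chosen after the results were seen. Genes called in opposite directions in the comparisons of Active and of UVB with Quiescent numbered 53, and each of the 53 also passed the direct test of UVB against Active in edgeR. That adds little, since genes chosen for opposite changes from the same Quiescent libraries differ between UVB and Active by the sum of both. Of these, 35 were lower in Active and higher in UVB than in Quiescent, among them the collagen gene Col7a1 (log2 fold changes -2.37 and 1.60). Another 18 were higher in Active and lower in UVB, among them the ribonuclease gene Rnase1 (2.27 and -1.98). Col7a1 and Rnase1 were picked after their values were seen. With library size alone, which shifts both comparisons with Quiescent upward, 15 of the 53 were still called in opposite directions.

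In UVB against Active, pigment genes were lower, and genes of fibroblasts, vessels, myeloid cells, T cells and mast cells higher. Fewer melanocyte lineage cells in the UVB sort would lower lineage and pigment genes alike. The tables argue against this as the whole account, because the lineage list median lay 2.63 log2 units above the pigment list median (bootstrap interval 2.13 to 3.58), although several lineage genes are also made by other skin cells. A general rise of every other skin cell type was not seen in the suprabasal keratinocyte list. Its median was -2.06 (interval -2.58 to -1.40), with 3 of 16 members lower and 0 higher. A fall of that list is not established, since camera with an estimated correlation gave adjusted p = 0.492. The same limit holds for the other lists of this pattern, since no list passed that test and the lowest adjusted p was 0.445. Both intervals are over list members, which can vary together, and hold no spread between libraries. Immune cells in the UVB sort cannot be told apart from a change of state within the sorted cells for the myeloid, T cell and mast cell lists. The count of 37 of 42 members higher, 1 of which, Thy1, also stands in the fibroblast list, restates the pattern and supports neither, so both stay open.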

How the results depend on the processing

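Library size alone, the groups of removed genes or libraries and the 2-fold test were chosen after the data were examined. Under the scaling, filter, tool and FPKM alternatives fixed in advance, totals of changed genes stayed within 1.5 times the reported ones, at 8138 to 9153, 6243 to 7934 and 3317 to 4642 for Active against Quiescent, UVB against Quiescent and UVB against Active, with no gene called in the opposite direction. Leaving out 1 library at a time gave 7522 to 8938, 5901 to 7492 and 1452 to 4226 genes, of which 3843 to 4452, 3214 to 3865 and 999 to 2548 were higher and 3679 to 4486, 2687 to 3728 and 453 to 1678 lower. In UVB against Active the low counts were 1806 without Active replicate 1, 1452 without Active replicate 2, and 1938 without UVB replicate 1 and the cause was not tested. The test beyond 2-fold, stricter by construction, gave 3599 (1608 higher, 1991 lower), 2317 (1377 and 940) and 826 (708 and 118), and 2017 genes alike in both comparisons with Quiescent against 5959. Library size alone gave 8651 higher and 2206 lower in Active against Quiescent and 8746 and 1246 in UVB against Quiescent, because it moves the median log2 fold change of all genes from 0.007 to 0.757 and from 0.021 to 0.742. With it, 285 and 269 genes were called in the opposite direction. Braf in Active against Quiescent reversed to 0.55. Lists whose median changed sign with library size alone include NF-kB targets (0.24) and cell cycle inhibitors (0.22) in UVB against Quiescent and mast cell genes (0.61) in Active against Quiescent. With an estimated correlation, 0, 0 and 0 lists passed camera, against 15, 12 and 16. The runs differed only in how the correlation between members was set. In Active against Quiescent it was estimated at 0.942 for mitosis and 0.048 for nucleotide excision repair, against the preset 0.01, and both lists lost their call. How far the size of the correlation alone drives this was not tested. Removing X and Y genes left 8486, 7118 and 3471 calls, removing the fibroblast list 8799, 7405 and 3599, and leaving out Quiescent replicate 2 with UVB replicate 3 8300, 7378 and 3054. Replicate numbers gave no clear sign of pairing: deviations of same-numbered libraries correlated at -0.171 to 0.231, and of differently numbered ones at -0.209 to 0.26. With 3 libraries per group this cannot exclude a pairing. With the replicate block, 8223, 6809 and 2830 genes were called and 5528 alike, and libraries did not all correlate best with their own number. For the 189 results for named genes, a change of direction was counted only where 1 of the 2 fits compared called the gene. By that count, 189 kept their direction and call with RLE and with upper-quartile factors. With DESeq2 186 did (Cd163 and Krtap11-1 in UVB against Active lost their call). The FPKM fits (pseudocounts 1 and 0.1) kept 187 and 188, the fit without a filter 188, the strict filter 188 and the block 187. With library size alone 186 did, and 170 in the test beyond 2-fold, where 19 lost their call. With only the 2 groups compared 185 did, and Hmga2 and Mitf in UVB against Quiescent gained a call. In fits with 1 library left out, calls were lost 27 times and gained 4 times. Braf in UVB against Active lost its call in both FPKM fits, without a filter and with the block. Lists passing camera numbered 13 to 17, 10 to 14 and 15 to 19 with 1 library left out, and 16, 16 and 16 with the replicate block. Leaving out libraries ended camera calls of lists not named in the report with a camera value: immediate early genes in Active against Quiescent (adjusted p = 0.11 without Quiescent replicate 2, 0.13 without it and UVB replicate 3), TGF-beta targets in UVB against Quiescent (0.11 without Quiescent replicate 2, 0.065 and 0.057 without UVB replicates 2 and 3, 0.11 without Quiescent replicate 2 and UVB replicate 3) and oxidative stress genes in UVB against Active (0.082 without Active replicate 1). In simulation, few changes of 1.5 times were recovered. Far fewer genes were changed there than were called here, which makes the adjusted threshold harder to pass. Those shares may therefore understate what the comparisons could detect.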

Other observations

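The tests of explanations and the splits in this part were chosen after the results were seen. Of 15 genes of Schwann cells, glia that share the neural crest origin of melanocytes, 8 rose and 3 fell in Active against Quiescent, and 9 rose and 2 fell in UVB (8 and 3, and 9 and 3, adjusted over the list alone). Camera did not pass the list in Active (adjusted p = 0.061, and adjusted p = 0.753 with an estimated correlation), but did without Active replicate 1, 2 or 3 (adjusted p = 0.025, 0.037 and 0.03). In UVB the list passed (adjusted p = 0.023, and adjusted p = 0.803 with an estimated correlation), but not without UVB replicate 3 (0.057), nor without it and Quiescent replicate 2 (0.075). Cdh19, a cadherin, had 1.54 ± 0.163 CPM in Quiescent, 220 ± 61.6 CPM in Active and 239 ± 21.1 CPM in UVB, and Sox2 0.223 ± 0.0778, 33.3 ± 15.9 and 47.0 ± 10.2 CPM. The adhesion genes L1cam and Cdh2 rose 69.9-fold and 35.9-fold in Active and 75.9-fold and 42.8-fold in UVB. Cdkn2a, a cell cycle inhibitor locus, rose along with the division genes, from 1.07 ± 0.176 to 49.9 ± 10.1 CPM in Active and 46.4 ± 10.4 CPM in UVB. Lrig1, a restraint on growth factor receptors, fell 7.49-fold and 3.28-fold. The glycolytic genes Ldha and Pgk1 rose 3.5-fold and 5.09-fold in Active and 2.76-fold and 3.49-fold in UVB, and the list as a whole was mixed, with 10 higher and 7 lower of 21 in Active, and 10 and 5 in UVB (11 and 9, and 10 and 5, adjusted over the list alone).

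Between UVB and Active, the mesenchymal transcription factors Snai1 and Twist1 were 9.94-fold and 9.19-fold higher in UVB, and Lox, which cross-links collagen, 17.6-fold higher (10.6-fold without UVB replicate 3), within a migration list of which 8 of 28 rose and 2 fell, also adjusted over the list alone. Ltbp2, a matrix protein of the TGF-beta list, rose 12.2-fold, and 8 of 20 members of that list rose, also adjusted over the list alone. Dkk2, a secreted Wnt modulator, had 60.1 ± 22.5 CPM in Quiescent, 1.94 ± 0.149 CPM in Active and 46.4 ± 21.5 CPM in UVB. Dermal fibroblast genes rose in UVB as well. Oxidative stress genes fell for 4 of 18 members, also adjusted over the list alone, with Gpx4 2.07-fold and Prdx1 1.87-fold lower.

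The Quiescent libraries carried abundant fibroblast transcripts and few of the melanocyte lineage. Scaling distorted by a few abundant genes is argued against for these 2 lists, whose medians in Active against Quiescent kept their direction under other scalings. Some list medians near 0 did not: with library size alone, MHC class I went from -0.06 to 0.69 and mast cell genes from -0.12 to 0.61. The fibroblast list median was -5.04 with TMM factors and -4.29 with library size alone (bootstrap interval -6.07 to -1.40). Library size alone keeps the weight of abundant genes, and with it the lineage list median was 4.1. Leaving out the fibroblast list before scaling gave 8799 calls against 8786. The lineage list median was 3.36 (interval 1.52 to 5.69) and Sox10 averaged 2.16 CPM in Quiescent. Melanocyte stem cells at rest that keep their lineage genes would not give such values as the bulk of these libraries. These values are part of the pattern itself, however, and no separate test. Dermal fibroblasts in the Quiescent sort cannot be told apart from a resting state that silences lineage genes and makes collagen. All 16 fibroblast genes were lower in Active, but that count restates the pattern and supports neither, so both stay open for the fibroblast genes. Also lower in Active were 12 of 13 endothelial, 11 of 11 muscle and 12 of 19 myeloid genes (12, 11 and 13 adjusted over each list alone). Of the endothelial genes 1 was higher. Tek had 86.0 ± 12.8 CPM in Quiescent and 1.73 ± 0.298 CPM in Active, and Myh11 240 ± 46.0 and 13.4 ± 4.66 CPM. A resting state that makes collagen does not cover endothelial and muscle genes, so these lists argue against it as the whole account. Dermal fibroblasts alone do not cover them either. Other cell types in the Quiescent sort were not tested as a source of these lists.

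The UVB libraries had the sex-linked transcripts of female animals, and the Quiescent and Active libraries those of males. Female animals in the UVB group are a candidate explanation, which rests mainly on Xist and the Y-linked genes, since these set every UVB library apart from every other. All 4 X-linked partners of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were also higher in UVB than in Active. Against Quiescent, 3 of the 4 were higher in UVB and 2 in Active, so sex was not the whole source of their change. In UVB against Active, 22.3% of 502 X-linked genes and 24.0% of autosomal genes were called. Autosomal genes that differ by sex cannot be told apart from an effect of UVB among the 3490 autosomal calls, because no group held both patterns of sex-linked transcripts.

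Other splits of the libraries into groups of the same sizes were fitted in the same way. In Active against Quiescent, 1 of 10 splits, the real one, gave as many as 8786 genes, and the highest other gave 0. In UVB against Quiescent it was again 1 of 10, with 7393 against 1, and in UVB against Active 1 of 10, with 3612 against 0. For lists, 3, 5 and 5 of 10 splits gave as many as 15, 12 and 16, and the highest others gave 18, 18 and 22. These 10 splits are too few for a share under 0.05. For genes called alike, 1 of 100 splits, the real one, gave as many as 5959, and the highest other gave 5022. Splits that mix Quiescent libraries with others place group differences within groups, which tends to leave few calls. The share of 1 in 100 therefore cannot exclude chance for the overlap. The 2 drawn splits that kept the Quiescent libraries together and mixed Active with UVB gave 5022 and 4913, so the count follows the separation of Quiescent from the rest and does not show that Active and UVB are alike.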
